A study of Homo sapiens with 6 samples.

How the data were processed

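The data were 6 RNA-seq libraries of MOLM-13 cells, 2 for each of 3 groups: a scrambled shRNA, and 2 shRNAs against YTHDC1, called shRNA 1 and shRNA 2. Per the labels' protocols, RNA was extracted with TRIzol and made into mRNA libraries with a TruSeq RNA kit that does not mark strand. Groups were read from the treatment label of each sample. Replicate numbers only name a library within its group and pair nothing.

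Per the submitters' processing notes, FastQC, STAR 2.7.2b, edgeR and limma were used with the hg38 genome build. The counting tool and the annotation release behind the counts are not given in the sources used here. The authors deposited a table of raw counts, whole numbers per Ensembl gene and library that were not normalized, and every comparison rests on it. Of its 60886 rows, some repeated a gene: 226 gene identifiers were on more than 1 row, and 2 of these had differing values. The row with the larger total was kept, which left 60623 genes. The authors deposited another table, whose name gives it as CPM, counts scaled to the library total. All 294820 of its values above 0 equalled a count scaled to CPM with 1 of the 6 library totals, within a relative tolerance of 1e-05. Only 16.7% of them were divided by the total of their own library, so the columns are not on a common scale, and that table was used in no comparison.

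Symbols came from a table of Ensembl identifiers and current symbols, which matched 60295 of the genes. Gene positions, gene types and exon lengths came from GENCODE release 29 on GRCh38, the same assembly as hg38, which held 58516 of the genes. That release may not be the one the authors counted on. Positions are 1-based.

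Depth was the sum of counts over genes, from 1743278 to 5232574 per library. The 2 libraries of each group differed by more than sampling noise: the chi-square per gene between them was 2.83, 4.09 and 2.61 for scramble, shRNA 1 and shRNA 2, over genes with a summed count of at least 20. All were counted as separate samples. Background was estimated per library from 381 olfactory receptor genes, with 899 kb of exons in all, as RPKM (counts per kb of exon, scaled to the library total) computed from the deposited counts. That density times the 134.9 Mb of annotated exons gave the estimated background share of the counts. This estimate was introduced after the counts had been looked at, and it assumes 1 density over all exons.

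Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which kept 35584, and libraries were scaled with TMM factors between 0.912 and 1.091. A model of 3 group means was fitted over all 6 libraries with glmQLFit, robust, and tested with glmQLFTest. Contrasts were shRNA 1 minus scramble, shRNA 2 minus scramble, and shRNA 2 minus shRNA 1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of the F statistic. Gene lists were tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 33 lists. A list counted for both shRNAs when it was called the same way in both contrasts. With an estimated correlation, camera uses only the residual degrees of freedom, which are few with 6 libraries and 3 group means. Adjusted p-values rise there even for lists whose genes barely correlate. A call lost in that setting therefore does not by itself show correlated genes. CPM values in the text were computed from the deposited counts with the TMM-scaled library sizes.

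The groups, the tests, the 33 lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named YTHDC1 and MCM2 to MCM7. It also named up to 10 genes higher and 10 lower with both shRNAs by the smaller of the 2 absolute log2 changes, with a mean of at least 5 CPM and a gene symbol. Clone, microRNA and pseudogene names were excluded, and that exclusion was widened to small RNA pseudogenes and family names once such names had appeared. Up to 4 called members per list, or else the 2 most abundant, and the 6 genes most different between the shRNAs in each direction completed the 93 named genes. Genes named outside this rule are said to be so. The MCM2-7 list was taken from the title of the series, so it is not independent evidence of its own direction.

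Alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors, no count filter, at least 1 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, fits of only the 2 groups compared, an absolute log2 change of at least 1, camera with an estimated correlation or on voom values, and leaving out each library. After the data had been seen, 4 more were added. These were a fit of the 2714 expressed protein-coding genes only (mean of at least 10 RPKM, library sizes and TMM recomputed), the same with lincRNA genes, all genes scaled with the library sizes and TMM factors of the expressed genes, and expressed genes after subtracting the background density times exon length. The choice of protein-coding genes alone as the expressed set was made after both versions had been run.

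The comparisons with the 2 shRNAs share their scramble libraries. Unchanged groups were therefore simulated from the scramble means and the fitted dispersions, 20 times, and tested in the same way. Dilution alone was simulated likewise for the expressed genes, from the scramble signal and each library's background, and tested after subtracting that same background. Random lists for comparison, 10000 per list, were drawn from the 100 protein-coding or lincRNA genes nearest in RPKM to each member. The rise that background allows with shRNA 1 was the ratio of the highest shRNA 1 to the lowest scramble background density per effective library size, and larger rises were tested with edgeR glmTreat over all genes. The tests were checked on simulated counts for the 35584 genes, with 100 genes changed 2-fold and 100 changed 4-fold in each shRNA comparison. At a 2-fold change 26% were recovered in each shRNA comparison, and at 4-fold 69% with shRNA 1 and 68% with shRNA 2. Among genes with a mean count of at least 50, a 2-fold change was recovered for 57.5% with shRNA 1 and 60% with shRNA 2, and a 4-fold change for 95.1% with each. Each comparison made 7 calls among unchanged genes. A list lowered 2-fold in simulated shRNA 2 libraries was called, and 0 of the 32 other lists were. Genes were simulated independently, so this check does not cover lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Levels of genes on the Y chromosome and of XIST are not reported. A gene withheld for evaluation is not reported here by name, and is kept in the gene counts and list tests.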

Results

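RNA sequencing was carried out on MOLM-13 cells, a human acute myeloid leukaemia line, carrying a scrambled short hairpin RNA (shRNA) or either of 2 shRNAs against YTHDC1. YTHDC1 is a nuclear protein that binds N6-methyladenosine (m6A) in RNA. Each of the 3 groups had 2 libraries. Total counts were 3119536 and 2232229 for scramble, 5232574 and 2996274 for shRNA 1, and 1743278 and 3232963 for shRNA 2. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

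The libraries differed in how many counts fell on genes that blood cells are not known to use. The 381 olfactory receptor genes, taken as a measure of background, had a density of 2.51 ± 0.069 RPKM with scramble, 2.82 ± 0.327 with shRNA 1 and 3.51 ± 0.146 with shRNA 2 (SD, n = 2 each). Spread over all annotated exons, this density corresponded to 33.9 ± 0.933%, 38.0 ± 4.41% and 47.3 ± 1.97% of the counts (SD, n = 2 each). Mitochondrial ribosomal RNA took 5.80 ± 0.771%, 7.06 ± 0.672% and 9.04 ± 1.23% of the counts in the same order (SD, n = 2 each). MALAT1, a nuclear long noncoding RNA, took 6.85 ± 0.488% with scramble, 3.60 ± 0.467% with shRNA 1 and 3.45 ± 0.092% with shRNA 2 (SD, n = 2 each).

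**Figure D1:**
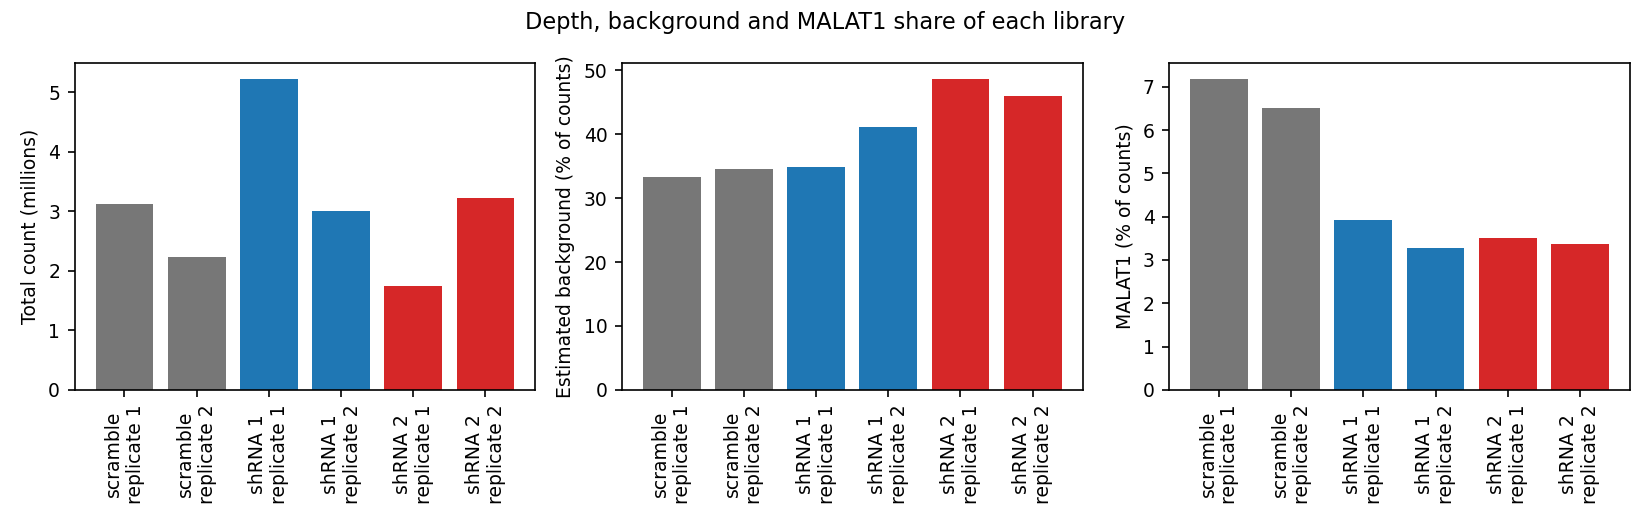
Bars show, for each of the 6 libraries, the total count, the estimated background as a percentage of counts, and the share of counts on MALAT1. The estimated background is 48.7% and 45.9% in the shRNA 2 libraries and between 33.2% and 41.1% in the other 4, and MALAT1 is at 7.19% and 6.50% with scramble against 3.27% to 3.93% in the other libraries.

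Fold changes moved with the density of counts on a gene. Protein-coding genes of at least 50 RPKM, 128 genes, had a median log2 fold change of -0.36 with shRNA 1 and -1.28 with shRNA 2, while the 3453 genes under 3 RPKM had medians of 0.18 and 0.07. Scaling on the 2714 expressed protein-coding genes instead of on all tested genes raised log2 fold changes by 0.22 with shRNA 1, 0.56 with shRNA 2 and 0.35 for the difference between the shRNAs. Directions below are relative to all tested genes, and the value scaled on expressed genes, a setting chosen after seeing the data, is given where it ends a named gene's call against scramble. List tests compare a list with the other tested genes, so after that scaling a list called lower can have a median above 0.

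The first comparison asked whether YTHDC1 itself was lower with each shRNA. YTHDC1 (ENSG00000083896, GRCh38 chromosome 4, 68310387 to 68350089) stood at 297 ± 6.83 CPM with scramble, 239 ± 33.3 CPM with shRNA 1 and 174 ± 22.6 CPM with shRNA 2 (SD, n = 2 each). Its counts were 846 and 595 with scramble, 1324 and 654 with shRNA 1, and 353 and 535 with shRNA 2. YTHDC1 fell by 0.78 ± 0.155 on the log2 scale (SE) with shRNA 2, 1.72-fold lower (edgeR adjusted p = 0.000384). With shRNA 1 the log2 fold change was -0.31 ± 0.151 (SE) and did not pass the test (edgeR adjusted p = 0.468). The difference between the shRNAs did not pass either (edgeR adjusted p = 0.0825). Scaled on expressed genes, the log2 fold changes of YTHDC1 were -0.09 (edgeR adjusted p = 0.805) and -0.22 (edgeR adjusted p = 0.238). In a fit of expressed genes with lincRNAs that with shRNA 2 was still called (log2 -0.44, edgeR adjusted p = 0.0229). As the call depends on the scaling, the groups are named by their labels throughout. Without shRNA 2 replicate 2, the fall with shRNA 2 had an edgeR adjusted p of 0.0761.

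The second comparison asked which genes changed the same way with both shRNAs. Among those lower with both were genes of myeloid granules. MPO, which encodes the myeloperoxidase of primary granules (ENSG00000005381, chromosome 17, 58269856 to 58280935), went from 1676 ± 264.5 CPM with scramble to 604 ± 156 CPM with shRNA 1 and 330 ± 0.16 CPM with shRNA 2 (SD, n = 2 each), 2.77-fold and 5.08-fold lower. SRGN, the proteoglycan core protein of secretory granules (chromosome 10, 69088106 to 69104811), was 2.67-fold and 3.92-fold lower. LYZ, encoding lysozyme (chromosome 12, 69348341 to 69354234), was 2.39-fold and 3.92-fold lower, and ELANE, encoding neutrophil elastase (chromosome 19, 851014 to 856247), 2.01-fold and 5.89-fold lower. THBS1, encoding thrombospondin 1 (chromosome 15, 39581079 to 39599466), was 3.14-fold and 2.92-fold lower.

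In all, 263 genes were called lower with both shRNAs and 6 higher with both, of 35584 tested. The log2 fold changes of MPO were -1.47 ± 0.151 and -2.35 ± 0.157 (SE, edgeR adjusted p = 6.33e-09 and 1.17e-15). Those of SRGN were -1.42 ± 0.148 and -1.97 ± 0.154 (SE, edgeR adjusted p = 6.82e-09 and 2.87e-13), and those of THBS1 -1.65 ± 0.157 and -1.54 ± 0.159 (SE, edgeR adjusted p = 8.21e-10 and 4.39e-10). EEF1B2, a subunit of the translation elongation factor 1 complex, was 2.19-fold and 3.30-fold lower. BEX1 (log2 -1.25 and -2.11), NIFK (-1.23 and -1.56), NKG7 (-1.13 and -2.05) and the mast cell genes TPSAB1 (-2.28 and -2.16) and CPA3 (-1.49 and -1.61) were also called lower with both. TPSAB1 shares sequence with other tryptase genes and is uncertain. Of these, NKG7 was no longer called with shRNA 1 when scaled on expressed genes (log2 -0.93, edgeR adjusted p = 0.139).

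**Figure D2:**
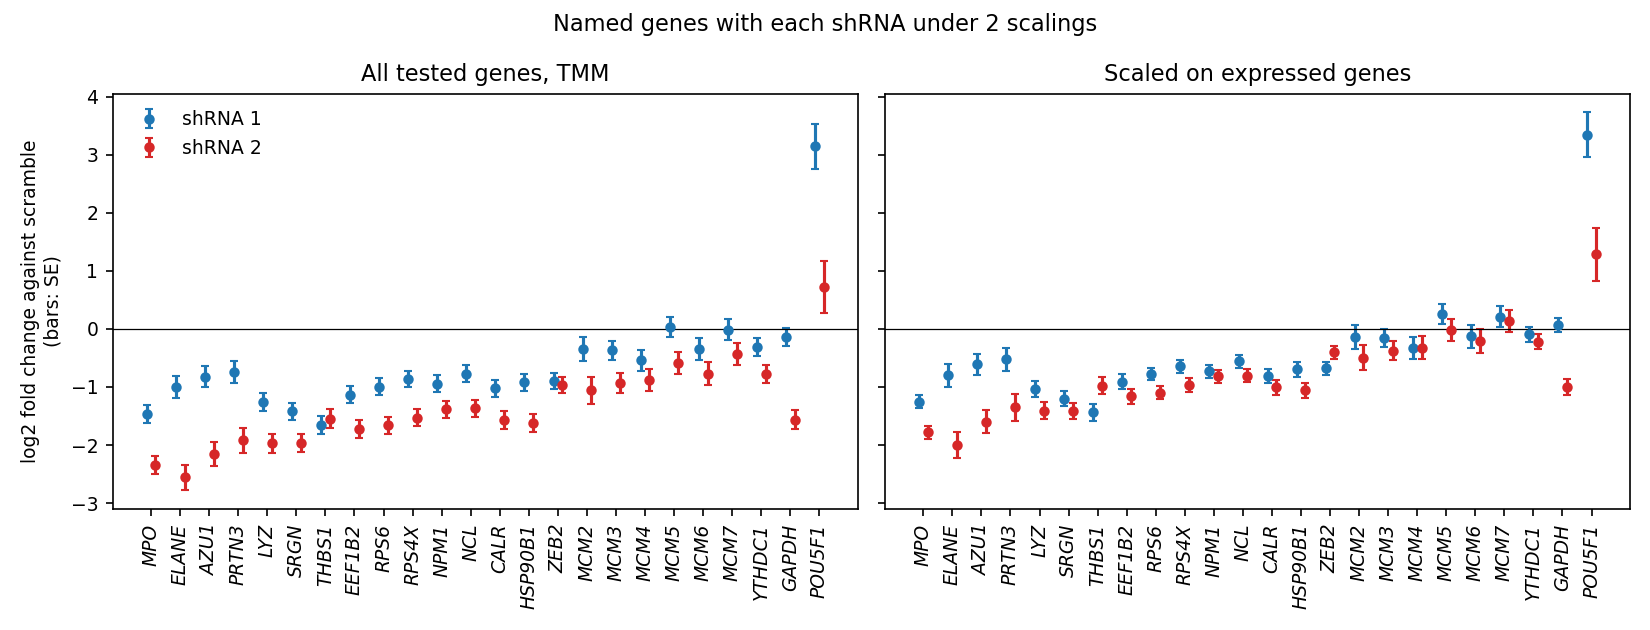
Points show the log2 fold change against scramble of 24 named genes with shRNA 1 and shRNA 2, with bars of 1 SE, tested over all genes (left) and scaled on expressed genes (right). MPO lies at -1.47 and -2.35 on the left and at -1.26 and -1.78 on the right, while YTHDC1 moves from -0.31 and -0.78 to -0.09 and -0.22; MCM5 and GAPDH with shRNA 1 and MCM7 with both lie above 0 on the right.

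Among the lists, granulocyte and primary granule markers were lower with both shRNAs (median log2 -0.30 and -0.55, camera adjusted p = 3.79e-06 and 1.39e-12; adjusted p = 0.359 and 0.107 with an estimated correlation). Of 21 measured members, 4 were lower with both: MPO, ELANE, AZU1 and PRTN3, which encode proteins of the primary granule. Adjusted over the list alone, 8 members were lower with each shRNA. The estimated correlations of the list were -0.005 and -0.007, under the preset 0.01. Its lost calls with an estimated correlation thus came with the fewer degrees of freedom of that test. AZU1 and PRTN3 were not called with shRNA 1 when scaled on expressed genes (edgeR adjusted p = 0.0911 and 0.226). The monocyte and macrophage list was also called lower (median log2 -0.22 and -0.17, camera adjusted p = 0.000814 and 0.00529; adjusted p = 0.375 and 0.217 with an estimated correlation), but LYZ was the only member of 23 called with both. ITGA2B, an integrin chain of platelets, was the member called with both in the erythroid and megakaryocyte list (log2 -0.94 and -1.30; list median -0.49 and -0.28, camera adjusted p = 0.000814 and 0.0118; adjusted p = 0.375 and 0.172 with an estimated correlation). In the leukaemia and stem cell programme, ZEB2, KIT and CDK6 were lower with both, with log2 fold changes of -0.90 and -0.97, -0.77 and -0.84, and -0.64 and -1.48. That list was called (median log2 -0.13 and -0.57, camera adjusted p = 0.00582 and 1.72e-07; adjusted p = 0.375 and 0.107 with an estimated correlation). KIT was called with neither shRNA, and CDK6 not with shRNA 1, when scaled on expressed genes (edgeR adjusted p = 0.214 and 0.352 for KIT, and 0.161 for CDK6).

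Some genes of the translation machinery were lower with both shRNAs. Of 76 cytosolic ribosomal protein genes, 24 were called lower with shRNA 1, 68 with shRNA 2 and 24 with both, and none higher. Adjusted over the list alone, 49 were lower and 1 was higher with shRNA 1, and 73 were lower with shRNA 2. The list medians were -0.43 and -1.31 on the log2 scale (camera adjusted p = 1.62e-32 and 2.09e-150; adjusted p = 0.375 and 0.107 with an estimated correlation). RPS6 was 1.99-fold and 3.16-fold lower (log2 -0.99 ± 0.142 and -1.66 ± 0.146, SE), RPS4X was at log2 -0.86 and -1.53, and RPS3A at -0.86 and -1.65. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain where reads were shared. The list of MYC and ribosome biogenesis genes was lower as well (median log2 -0.17 and -0.51, camera adjusted p = 0.000116 and 2.14e-12; adjusted p = 0.375 and 0.107 with an estimated correlation). The nucleolar proteins NPM1 (log2 -0.94 and -1.38) and NCL (-0.77 and -1.37), with NOP58 (-0.82 and -1.51) and DKC1 (-0.74 and -0.98), were its members called with both. Scaled on expressed genes, NOP58 was not called with shRNA 1 and DKC1 with neither (edgeR adjusted p = 0.134 for NOP58, 0.237 and 0.153 for DKC1).

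The endoplasmic reticulum chaperones CALR, encoding calreticulin (log2 -1.02 ± 0.147 and -1.57 ± 0.151, SE), and HSP90B1 (-0.92 ± 0.148 and -1.62 ± 0.154, SE) were the 2 members of the unfolded protein response list called with both, of 15. The list was called lower (median log2 -0.27 and -0.79, camera adjusted p = 0.000489 and 4.95e-15; adjusted p = 0.375 and 0.107 with an estimated correlation). The cytosolic chaperones HSP90AB1 (-0.91 and -1.38) and HSP90AA1 (-0.62 and -1.15) were lower with both, although their heat shock list was called only with shRNA 2 (median log2 -0.07 and -0.81, camera adjusted p = 0.782 and 4.92e-11; 0.107 with shRNA 2 with an estimated correlation). HSP90AA1 was not called with shRNA 1 when scaled on expressed genes (edgeR adjusted p = 0.0565). The difference between the shRNAs in the heat shock list passed the test (camera adjusted p = 3.25e-12; adjusted p = 0.14 with an estimated correlation).

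Another 4 lists were called lower with both shRNAs, of which 3 had no member called with both. The MCM2-7 genes encode the replicative helicase that the title of the series names. They had median log2 fold changes of -0.35 and -0.83 (camera adjusted p = 0.0388 and 2.25e-07; adjusted p = 0.375 and 0.107 with an estimated correlation), and as the study chose the list, this is not independent evidence of its direction. MCM2 (log2 -1.06), MCM3 (-0.94), MCM4 (-0.88), MCM5 (-0.59) and MCM6 (-0.77) were called lower with shRNA 2, MCM7 was at -0.43 (edgeR adjusted p = 0.216), and none was called with shRNA 1, where values ran from -0.54 for MCM4 to 0.04 for MCM5. Adjusted over the list alone, 1 member was lower with shRNA 1 and 6 with shRNA 2. No MCM gene was called with either shRNA when scaled on expressed genes (edgeR adjusted p from 0.0978 to 0.945 with shRNA 2), while the list kept its call with shRNA 2 (median -0.27, camera adjusted p = 0.000255) and lost it with shRNA 1 (-0.14, camera adjusted p = 0.246). Among expressed genes only, none of the 5 MCM genes in the set was called with either shRNA, and MCM7 was above 0 with both and MCM5 with shRNA 1. There the list had, with shRNA 1, a median of -0.13 with a test pointing higher (camera adjusted p = 0.914), and with shRNA 2 -0.21 (camera adjusted p = 0.575). E2F targets (median log2 -0.11 and -0.42, camera adjusted p = 0.0456 and 6.40e-05), m6A readers other than YTHDC1 (-0.11 and -0.76, camera adjusted p = 0.0456 and 9.69e-10) and nucleotide synthesis genes (-0.13 and -0.52, camera adjusted p = 0.0411 and 2.94e-06) were the others. With an estimated correlation their adjusted p-values were between 0.107 and 0.56. IMPDH2, which catalyses a step of guanine nucleotide synthesis, was the 1 nucleotide synthesis gene called with both (log2 -0.74 and -1.19), and it was not called with shRNA 1 when scaled on expressed genes (edgeR adjusted p = 0.136).

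The 6 genes higher with both shRNAs became 101 when scaled on expressed genes, where 87 were lower with both, so the balance depends on the scaling; they became 0 with the DESeq2 Wald test and 1 with limma-voom or in fits of only the 2 groups compared. Of the 6, those with a symbol that met the naming rule were CLDN6, a claudin (0.96 ± 0.662 CPM with scramble, 14.3 ± 3.91 with shRNA 1 and 6.33 ± 3.96 with shRNA 2), and IFITM10 (8.28 ± 0.1, 22.5 ± 2.43 and 22.0 ± 2.24 CPM, SD, n = 2 each). The counts of CLDN6 were 4 and 1 with scramble, 86 and 35 with shRNA 1, and 17 and 12 with shRNA 2. The 2 genes averaged 4.15 and 3.69 RPKM, and neither was in the expressed set. Markers of epithelial cells, kidney lines and fibroblasts were the 1 list called higher with both (median log2 0.38 and 0.33, camera adjusted p = 0.000814 and 0.0191; adjusted p = 0.375 and 0.143 with an estimated correlation), with a median density of 5.08 RPKM.

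The scramble libraries were common to both comparisons. Across genes, the log2 fold changes with the 2 shRNAs had a correlation of 0.538 and a covariance of 0.211, against 0.536 and 0.157 in 20 simulations of unchanged groups, and 66.5% of genes shared their sign, against 67.4%. Genes are not independent replicates. Simulated unchanged groups had on average 0.15 genes lower and 0.1 higher with both. Independent lists of the observed sizes would share 14.8 lower and 0.173 higher genes. Part of the excess may come from the shared controls, which were too few to be split. Among expressed genes only, 124 genes were lower and 12 higher with both, all 124 of them among the 263. There, independent lists of the observed sizes would share 20.8 lower and 7.8 higher genes. The count of 263 became 87 when scaled on expressed genes, 416 with limma-voom, 144 in fits of only the 2 groups compared, 76 without scramble replicate 1, 139 without scramble replicate 2 and 462 without shRNA 1 replicate 1. The 12 lists called with both shRNAs became 0 with an estimated correlation, where camera has few degrees of freedom. Some of the 12 also had estimated correlations over the preset 0.01. With shRNA 1 and shRNA 2 these were 0.28 and 0.30 for m6A readers, and 0.20 and 0.20 for MYC and ribosome biogenesis. They were 0.18 and 0.20 for the unfolded protein response, and 0.12 and 0.16 for MCM2-7. Granule markers and the leukaemia and stem cell programme were under the preset. Among expressed genes only the 12 lists became 3: ribosomal proteins, granule markers and unfolded protein response (0 of them there with an estimated correlation). When scaled on expressed genes they became 6. Of the 6, the medians of the MYC and ribosome biogenesis list (0.05 and 0.05) and, with shRNA 2, of the granulocyte and primary granule markers (0.01) and the erythroid and megakaryocyte markers (0.28) were above 0 after that scaling, with tests still pointing lower.

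**Figure D3:**
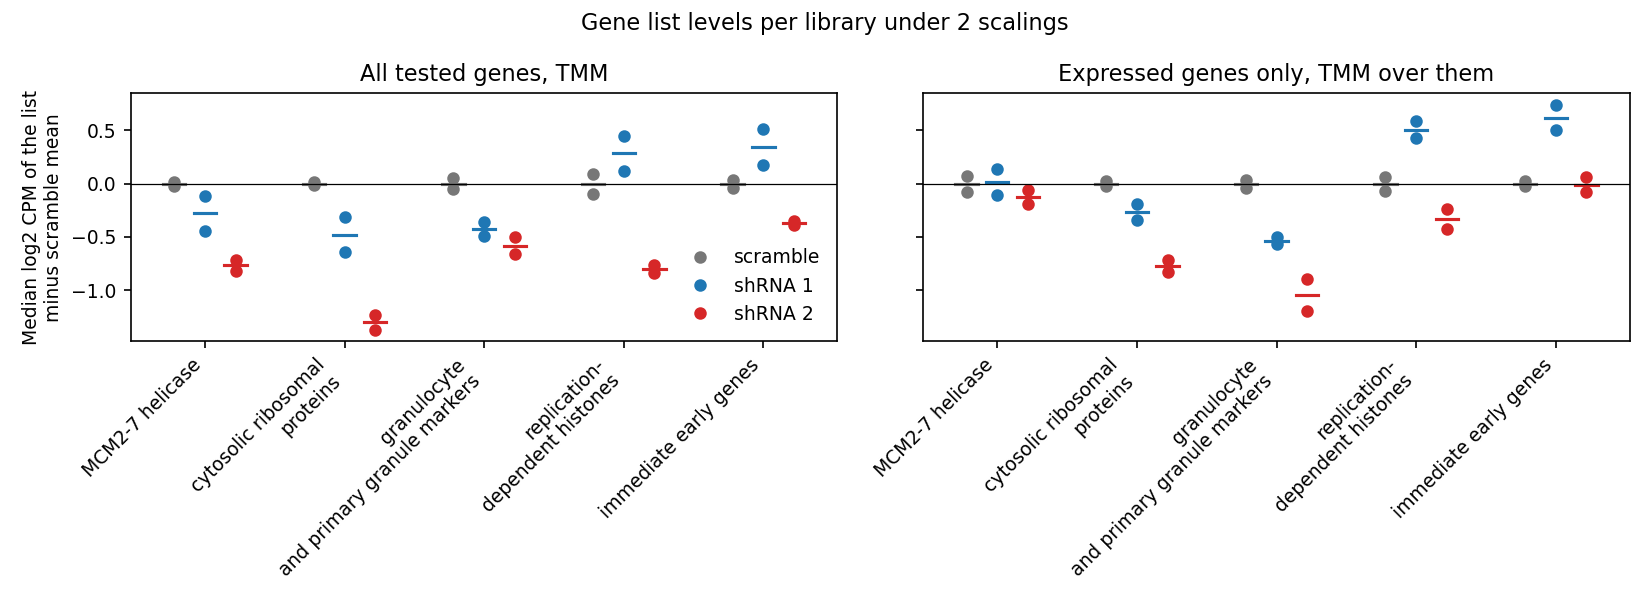
Each point is a library's median log2 CPM over the genes of a list, minus the scramble mean, scaled on all tested genes (left) or among expressed genes only (right), with bars at group means. Ribosomal protein and granule genes lie below 0 in all 4 shRNA libraries on both sides, MCM2-7 rises to between -0.19 and 0.14 on the right, and histone genes lie above 0 with shRNA 1 and below 0 with shRNA 2 on both sides. The right side holds only expressed members, so the sides differ in genes as well as scaling: 8 against 21 granule genes and 5 against 6 MCM2-7 genes.

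With shRNA 1 taken alone, 57 genes were higher and 284 lower. Genes known from pluripotent and embryonic cells were among those higher. POU5F1, a transcription factor of pluripotent cells (chromosome 6, 31164337 to 31180731), was at 5.0 ± 1.51 CPM with scramble, 44.97 ± 19.3 CPM with shRNA 1 and 7.99 ± 3.71 CPM with shRNA 2 (SD, n = 2 each), a log2 fold change of 3.14 ± 0.381 with shRNA 1 (SE, edgeR adjusted p = 4.71e-07). ZIC2, a zinc finger factor of early neural development (log2 2.73, edgeR adjusted p = 0.00613) and APOE, an apolipoprotein (2.71, edgeR adjusted p = 0.00237), were higher too. APOE had 3 and 16 counts with scramble, and 197 and 42 with shRNA 1. ZIC2 had 6 and 5 counts with scramble, and 106 and 28 with shRNA 1. Its mean density of 1.9 RPKM was under the 2.51 RPKM estimated for background with scramble. POU5F1 was at 58.6 and 31.4 CPM in shRNA 1 replicates 1 and 2. The replication-dependent histone list was called higher (median log2 0.35, camera adjusted p = 0.000643; adjusted p = 0.482 with an estimated correlation), with 0 of 27 members called alone and 2 higher when adjusted over the list alone. Immediate early genes (0.35, camera adjusted p = 0.00284; adjusted p = 0.39 with an estimated correlation) and cholesterol synthesis genes (0.16, camera adjusted p = 0.0439; adjusted p = 0.375 with an estimated correlation) were called higher with no member called. With shRNA 2 these 2 lists were called lower, with medians of -0.39 (camera adjusted p = 0.00589) and -0.27 (camera adjusted p = 0.0146); adjusted p = 0.27 and 0.158 with an estimated correlation. Both calls with shRNA 2 ended among expressed genes only, with immediate early genes at -0.02 (camera adjusted p = 0.969) and cholesterol synthesis at 0.15 with a test pointing higher (camera adjusted p = 0.53). Of the calls with shRNA 1, 83.3% were lower, against 64.9% among expressed genes only and 34.2% when scaled on expressed genes. The 57 higher genes became 11 with the DESeq2 Wald test, 192 when scaled on expressed genes, 30 without scramble replicate 1, 136 without shRNA 1 replicate 2 and 91 without shRNA 2 replicate 1; the 284 lower genes became 100 when scaled on expressed genes, 481 with limma-voom, 149 in the fit of the 2 groups, 82 and 154 without scramble replicates 1 and 2, and 500 without shRNA 1 replicate 1.

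With shRNA 2 taken alone, 108 genes were higher and 1856 lower. GAPDH, a glycolytic enzyme often used as a reference gene (chromosome 12, 6533927 to 6538374), fell from 411 ± 19.2 CPM to 138 ± 17.3 CPM (SD, n = 2 each; log2 -1.56 ± 0.16 SE, edgeR adjusted p = 3.75e-10), and stood at 372 ± 86.7 CPM with shRNA 1 (SD, n = 2). It remained called when scaled on expressed genes (log2 -1.002, edgeR adjusted p = 1.09e-07). H1-5, a linker histone of S phase, was 3.60-fold lower (log2 -1.85 ± 0.203 SE, edgeR adjusted p = 3.78e-09), and 13 of 27 replication-dependent histones were lower (list median -0.85, camera adjusted p = 4.95e-15; adjusted p = 0.107 with an estimated correlation; median -0.34 and camera adjusted p = 0.154 among expressed genes only). HNRNPA2B1 (log2 -1.13), MDM2 (-0.92), ENO1 (-1.05) and SQSTM1 (-0.79) were lower with shRNA 2 and not called with shRNA 1. SQSTM1 was not called when scaled on expressed genes (edgeR adjusted p = 0.332). Lower calls made up 94.5% of the total, against 59.1% among expressed genes only and 7.1% when scaled on expressed genes, where 5459 genes were higher. The 1856 lower genes became 355 among expressed genes only, 416 when scaled on expressed genes, 1149 without scramble replicate 1, and 1212 and 1190 without shRNA 2 replicates 1 and 2; the 108 higher genes became 246 among expressed genes only, 23 with the DESeq2 Wald test, 59 with limma-voom, 199 and 164 without shRNA 1 replicates 1 and 2, and 51 and 64 without shRNA 2 replicates 1 and 2.

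Other lists were called lower with shRNA 2 and not with shRNA 1. These were replication fork (median log2 -0.33), G2/M and mitosis (-0.52), DNA repair (-0.28), p53 targets (-0.29), m6A writers and erasers (-0.18), SR proteins and splicing kinases (-0.58), ATF4 and integrated stress response (-0.25), glycolysis and hypoxia (-0.44), nuclear-encoded oxidative phosphorylation (-0.56), mitochondrially encoded mRNAs (-0.37) and lysosome and autophagy (-0.43). Their camera adjusted p-values with shRNA 2 were between 3.95e-14 and 0.0121, and with an estimated correlation between 0.107 and 0.334. Among expressed genes only, none of the 11 was called with shRNA 2, and the tests of replication fork, DNA repair, p53 targets, ATF4 and mitochondrially encoded mRNAs pointed higher. After background subtraction the mitochondrially encoded mRNAs were called higher with both shRNAs (median log2 0.22 and 0.42, camera adjusted p = 0.0273 and 0.000134). That test used the preset correlation of 0.01, while the correlation estimated for this list over all tested genes was 0.69 with each shRNA. An estimated correlation was not run after subtraction. Of the 13 members, 0 and 4 were called higher there. The mitotic genes MKI67 (log2 -0.71 and -0.89) and CENPF (-0.68 and -0.76), the splicing factor SRSF4 (-0.71 and -1.05), the m6A writer subunit ZC3H13 (-0.76 and -0.96) and the respiratory chain genes COX4I1 (-0.72 and -1.44) and COX7C (-0.94 and -1.21) were members called with both. Scaled on expressed genes, MKI67 and CENPF were called with neither shRNA (edgeR adjusted p from 0.0559 to 0.328), and SRSF4 and COX4I1 not with shRNA 1 (edgeR adjusted p = 0.098 and 0.185). Origin licensing factors, the BCL2 family, interferon response, NF-kB, and T and NK and B cell markers were called with neither shRNA (camera adjusted p between 0.0778 and 0.979). Among their most abundant members were ORC2 and MCM9, MCL1 and BCL2, EIF2AK2, NFKB1 and NFKBIA, and CD22 and EBF1, of which EIF2AK2 (log2 -0.82) was called lower with shRNA 2, though not when scaled on expressed genes (log2 -0.26, edgeR adjusted p = 0.326). Medians in these lists were -0.12 and -0.11 for origin licensing, 0.10 and -0.23 for the BCL2 family, -0.01 and 0.02 for interferon response, -0.02 and -0.15 for NF-kB, 0.07 and 0.14 for T and NK cells, and 0.06 and 0.08 for B cells. Median and test differed in sign for interferon response with shRNA 2 and for p53 targets with shRNA 1, and median and mean for these and for heat shock and interferon response with shRNA 1, none of them called.

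The third comparison was between the shRNAs, and 118 genes were higher and 1016 lower with shRNA 2 than with shRNA 1. The replication-dependent histone list differed by a median of -1.11 on the log2 scale (camera adjusted p = 3.91e-35; adjusted p = 0.14 with an estimated correlation), with 18 of 27 members lower with shRNA 2 than with shRNA 1. The list difference was also called among expressed genes only (median -0.83, camera adjusted p = 4.74e-10; adjusted p = 0.345 with an estimated correlation), where the list was called higher with shRNA 1 (adjusted p = 0.443 with an estimated correlation) but not lower with shRNA 2. H1-4, another linker histone, was at 0.47 with shRNA 1 and -0.98 with shRNA 2, a difference of -1.45 (edgeR adjusted p = 6.50e-07). The immediate early genes JUND (0.41 and -0.90) and IER2 (0.40 and -0.78) differed by -1.31 and -1.18, and their calls with shRNA 2 ended when scaled on expressed genes (edgeR adjusted p = 0.0986 and 0.282). GAPDH differed by -1.42 (edgeR adjusted p = 4.63e-08) and POU5F1 by -2.42 (edgeR adjusted p = 6.95e-06). Lower calls made up 89.6% of the 1134, against 65.2% of 353 among expressed genes only and 18.7% of 1516 when scaled on expressed genes. The total was 264 without shRNA 1 replicate 1, 1897 without shRNA 1 replicate 2, 473 and 567 without shRNA 2 replicates 1 and 2, and 669 with the DESeq2 Wald test.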

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

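The tests of the differences between the shRNAs were fixed before the data were examined, while the test of the pluripotency markers already looked at was chosen after the result was seen.

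The 2 shRNAs differed from each other in 1134 genes by the direct edgeR test, 1016 of them lower with shRNA 2. Among expressed genes only 353 differed, 241 of them shared with the 1134, and 401 were shared when scaled on expressed genes. Of the 33 lists, 23 differed. The replication-dependent histones (median log2 difference -1.11), cytosolic ribosomal proteins (-0.82), immediate early genes (-0.70), unfolded protein response (-0.58), heat shock (-0.57), cholesterol synthesis (-0.54) and p53 targets (-0.52) had the largest differences, all lower with shRNA 2. Next came MCM2-7 (-0.50), MYC and ribosome biogenesis (-0.47), glycolysis and hypoxia (-0.47), the BCL2 family (-0.46), G2/M and mitosis (-0.45), SR proteins (-0.45), granule markers (-0.45), m6A readers (-0.42) and lysosome (-0.40). Oxidative phosphorylation (-0.39), the leukaemia and stem cell programme (-0.39), nucleotide synthesis (-0.34), ATF4 and integrated stress response (-0.34), mitochondrially encoded mRNAs (-0.30), E2F targets (-0.27) and replication fork (-0.24) followed. With an estimated correlation, where camera has few degrees of freedom, no list difference passed (camera adjusted p = 0.14 or more). Of the 23, 6 were still called among expressed genes only: histones, ribosomal proteins, immediate early genes, heat shock, glycolysis and hypoxia, and granule markers; with an estimated correlation there, none was (adjusted p = 0.345 or more). In that set the tests of replication fork, E2F targets, p53 targets, the BCL2 family and mitochondrially encoded mRNAs pointed higher with shRNA 2, none of them called.

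Among named genes of granules, the log2 difference of shRNA 2 minus shRNA 1 was -1.55 for ELANE, -1.34 for AZU1, -1.17 for PRTN3, -0.88 for MPO, -0.72 for LYZ and -0.55 for SRGN. Genes of the translation machinery and the nucleolus differed by -0.79 for RPS3A, -0.75 for RPS21, -0.66 for RPS4X, -0.66 for RPS6, -0.69 for NOP58, -0.60 for NCL and -0.59 for EEF1B2. Histone and immediate early genes differed by -1.73 for H1-5, -1.45 for H1-4, -1.31 for JUND and -1.18 for IER2. Metabolic and stress genes differed by -1.42 for GAPDH, -1.02 for NFKBIA, -0.98 for FDFT1, -0.90 for SLC3A2, -0.81 for SQSTM1, -0.73 for MCL1, -0.72 for ENO1, -0.72 for COX4I1, -0.70 for HSP90B1, -0.55 for CALR and -0.52 for HSP90AA1. The remaining genes lower with shRNA 2 were CDK6 (-0.85), HNRNPA2B1 (-0.71), MCM5 (-0.62), XPC (-0.61), MDM2 (-0.60), LIG1 (-0.59), MCM3 (-0.57), ISYNA1 (-2.35), PUSL1 (-2.31) and RNVU1-29 (-2.56). SPATA31A1 (2.27), TRBV15 (2.17), KRTAP2-4 (1.76), SLC10A6 (1.74), VPREB1 (1.61) and SPTBN1-AS1 (1.56) were higher with shRNA 2. RNVU1-29, SPATA31A1, KRTAP2-4 and the antisense gene SPTBN1-AS1 can share reads with near-identical or overlapping genes and are uncertain. When scaled on expressed genes, the differences of LYZ, SRGN, RPS21, RPS4X, RPS6, NOP58, NCL, EEF1B2, SQSTM1, MCL1, ENO1, COX4I1, HSP90B1, CALR, HSP90AA1, HNRNPA2B1, MCM5, XPC, MDM2, LIG1, MCM3 and PUSL1 were not called (edgeR adjusted p from 0.0541 to 0.449). APOE, an apolipoprotein, differed by -2.86.

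The pluripotency markers ZIC2 and POU5F1 differed between the shRNAs by -2.90 and -2.42. Of 28 tested pluripotency markers that had been looked at, 9 were higher with shRNA 1 and 1 with shRNA 2, with medians of 0.80 and 0.12, and among them ESRG (2.69), SFRP2 (2.66), PODXL (1.39) and CD24 (1.24) were named after their values were seen. Scaled on expressed genes, 11 were higher with shRNA 1 and 8 with shRNA 2, so the contrast of 9 with 1 depends on the scaling; the direct difference was called lower with shRNA 2 for 7 markers, and for 4 after that scaling. The background densities allow a log2 rise of at most 0.14 with shRNA 1, or 0.49 scaled on expressed genes. Tested over all genes, 9 and 6 of the 28 markers rose by more than that. For the 6, this argues against background at a single density over all exons as the cause. The limit cannot exclude background that varies by gene, which stays open for the 6 as well. The others were not separated from a higher background share under both scalings. RNA from pluripotent cells was tested on 28 further markers. Of these, 0 were called higher with either shRNA, and 2 with shRNA 1 and 11 with shRNA 2 when scaled on expressed genes. With shRNA 1 their median lay at percentile 99.81 of random lists, which met the condition written beforehand. With shRNA 2 it lay at percentile 99.86, and for the difference at percentile 21.06. The condition was therefore made stricter after the result, and this test separates neither pluripotent RNA nor background. Both stay open for the further markers, and an effect of either hairpin on other transcripts, or of lower YTHDC1, was not tested.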

How the results depend on the processing

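The 4 alternatives built on expressed genes were chosen after the data had been seen, and the others before. No alternative chosen beforehand reversed a result. Under those, of the results for single genes, 2208 kept their direction and side of the threshold, 141 became weaker and 41 stronger; for lists these were 680, 66 and 22. Under the added alternatives they were 446, 101 and 27 for genes, with 6 reversed, and 139, 64 and 3 for lists, with 20 reversed. Sign changes between values that were never called count as the same. No paired analysis was possible because replicate numbers only name libraries in accession order. Without 1 library an arm has a lone sample, which is assumed to vary like the other groups. Genes near the background density have little depth, and the cause of the changes below was not tested unless stated.

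With the DESeq2 Wald test, 11 genes were higher with shRNA 1, 23 higher with shRNA 2, 0 higher with both (6 with edgeR) and 669 differed between the shRNAs. With limma-voom, 481 were lower with shRNA 1, 59 higher with shRNA 2, 416 lower and 1 higher with both. Fits of 2 groups gave 149 lower with shRNA 1, 144 lower and 1 higher with both. Upper-quartile factors gave 174 higher with shRNA 2. Requiring an absolute log2 change of at least 1 left 38 lower with shRNA 1, 700 lower with shRNA 2, 27 lower with both and 496 differing, by construction.

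Leaving out 1 library gave 30 to 136 genes higher and 82 to 500 lower with shRNA 1, 51 to 199 higher and 1149 to 2350 lower with shRNA 2, 3 to 14 higher and 76 to 462 lower with both, 264 to 1897 differing, and 7 to 15 lists. YTHDC1 ranged from -0.47 to -0.18 with shRNA 1 and from -0.92 to -0.67 with shRNA 2. MCM2-7 ranged from -0.45 to -0.14 with shRNA 1, and its call was lost without scramble replicate 1 (camera adjusted p = 0.0959), scramble replicate 2 (0.0534) or shRNA 1 replicate 2 (0.278); with shRNA 2 it ranged from -0.85 to -0.71.

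With an estimated correlation, where camera has few degrees of freedom, 0 lists were called, and MCM2-7 (-0.35 and -0.83) had camera adjusted p = 0.375 and 0.107. Among expressed genes only, 86 were higher and 159 lower with shRNA 1, 246 higher and 355 lower with shRNA 2, 12 higher and 124 lower with both, and 353 differed; 3 lists were called, and 0 with an estimated correlation. With lincRNAs, 179 were lower with shRNA 1, 300 higher and 685 lower with shRNA 2, 11 higher and 166 lower with both, 635 differed and 5 lists were called. Scaled on expressed genes, 192 were higher and 100 lower with shRNA 1, 5459 higher and 416 lower with shRNA 2, 101 higher and 87 lower with both, and 6 lists were called. After background subtraction, 125 were lower with shRNA 1, 233 higher and 308 lower with shRNA 2, 10 higher and 89 lower with both, 309 differed and 4 lists were called. YTHDC1 with shRNA 2 was at -0.22 among expressed genes, -0.22 scaled on them and -0.10 after subtraction, none called, and at -0.44 with lincRNAs, still called (edgeR adjusted p = 0.0229). MCM2-7 with shRNA 1 was at -0.13 (test pointing higher), -0.18 with lincRNAs, -0.14 scaled and -0.13 subtracted (test pointing higher), and with shRNA 2 at -0.21, -0.43 and -0.25 among expressed genes, with lincRNAs and subtracted, none called, and at -0.27 and still called when scaled (camera adjusted p = 0.000255).

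Reversed with shRNA 2 were HELLS (0.0109 among expressed genes, 0.0136 scaled, 0.0083 subtracted), ATM (0.0464 scaled), SLC3A2 (0.0265 subtracted) and ATF4 (3e-04 subtracted). So were the lists replication fork (0.26 expressed, 0.0437 with lincRNAs, 0.33 subtracted), E2F targets (0.0109 and 0.0083), DNA repair (0.23 and 0.29), p53 targets (0.35, 0.14 with lincRNAs, 0.45), ATF4 (0.0906 and 0.17), cholesterol synthesis (0.15 and 0.15) and immediate early genes (0.12 subtracted). Mitochondrially encoded mRNAs were at 0.19 expressed, -0.0202 with lincRNAs (test pointing higher), 0.19 scaled and 0.42 subtracted with shRNA 2, and at 0.22 subtracted with shRNA 1. After subtraction the list was called higher with both at the preset correlation (camera adjusted p = 0.0273 and 0.000134). An estimated correlation was not run in that fit. The test of MCM2-7 with shRNA 1, not in the counts above, also reversed among expressed genes only (median -0.13) and after subtraction (-0.13).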

Other observations

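The dilution tests of the expressed genes and of the genes lower with both shRNAs were chosen after the result was seen, and that of MCM2-7 before.

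MALAT1, a nuclear long noncoding RNA (chromosome 11, 65497688 to 65506516), fell with both shRNAs and was chosen after its values were seen. Its log2 fold change was -1.05 ± 0.142 (SE) with shRNA 1 and -1.22 ± 0.143 (SE) with shRNA 2, and the difference between the shRNAs had an edgeR adjusted p of 0.648. Scaled on expressed genes, MALAT1 was at -0.83 and -0.65, called with both.

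A few heat shock genes were higher with shRNA 1. DNAJB1, a co-chaperone (log2 0.68, edgeR adjusted p = 0.0336), and the inducible HSP70 genes HSPA1A (0.88, edgeR adjusted p = 0.0323) and HSPA1B (0.87, edgeR adjusted p = 0.0141) were called higher with shRNA 1, and were named after their values were seen, while HSP90AA1 and HSP90AB1 of the same list were lower with both shRNAs. With shRNA 2, HSPA1B was lower (-0.86, edgeR adjusted p = 0.012), and it was at -0.30 and not called when scaled on expressed genes. HSPA1A and HSPA1B are near-identical copies, so their counts are uncertain.

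The excess of genes lower with both shRNAs may come in part from dilution of transcripts by a higher background share. The median log2 change predicted for the 2714 expressed genes was -0.39 with shRNA 2 and -0.17 with shRNA 1. Measured medians were -0.54 and -0.20, which gave ratios of 0.715 and 0.873. The prediction used the background densities and the TMM factors fitted to the same counts. As those factors also enter the measured medians, the ratios do not give the share due to the densities alone. After subtracting the background from all expressed genes, 89 were still lower with both, all among the 263. This argues against dilution at a single density over all exons as the whole cause for these 89. In 20 simulations of dilution alone, with the scramble libraries shared by both comparisons, 0 genes were lower with both after the same subtraction. The simulations subtracted the same density that they had added, so a count near 0 was set in advance. Background that varies by gene was not simulated. Of the 263, 211 were in the subtracted fit. Dilution stays open for those not among the 89, and for the 89 where background varies by gene. An effect of lower YTHDC1 also stays open and untested. The estimated share was highest in both shRNA 2 libraries.

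MCM2-7 with shRNA 2 (median log2 -0.83) lay at percentile 1.23 of random lists matched on density, whose central 95% ran from -0.74 to 0.33. The condition written beforehand against dilution was met, but the series title names these genes, so the study chose them and their place among random lists excludes nothing. With the background densities and the TMM factors fitted to these counts, the predicted median was -0.41, a ratio of 0.49 to the measured value. As the same factors enter the measured value, that ratio does not give the share due to dilution alone. With shRNA 1 the list lay at percentile 11.76. Among expressed genes only, the median with shRNA 2 was -0.21 and the list was not called (camera adjusted p = 0.575), while over all genes scaled on expressed genes it was -0.27 and called (camera adjusted p = 0.000255). The camera test compares a list with the other genes in the fit, and these settings differ in those genes. Dilution stays open, and so does a fall of MCM2-7 with lower YTHDC1.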
